A study of Mus musculus with 10 samples.

How the data were processed

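RNA was measured on Affymetrix Mouse Gene 2.0 ST arrays in cortices of CD1 mouse embryos at embryonic days 12 to 13. Per the labels, 3 arrays held RNA precipitated with an antibody against 4E-T (4E-T replicates 1, 2 and 3), 3 held RNA precipitated with control IgG (IgG replicates 2, 3 and 4) and 4 held total RNA taken as input (input replicates 1 to 4). The design text speaks of 3 biological replicates of each kind of sample, while the labels list 4 inputs, and all 10 arrays were used.

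Precipitation used the Magna RIP kit and RNA was extracted with phenol and chloroform, per the labels' protocols. The same protocols name a BioAnalyzer check, amplification with a NuGEN Pico kit and biotin labelling with a WT Terminal Labeling kit. The deposited values are log2 intensities made by the authors with RMA (robust multi-array average, which corrects background, normalizes by quantiles and summarises probes) in Affymetrix Expression Console, per the submitters' processing notes. Software versions and the genome build behind the probe sets were not given in the sources used here.

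The table held 41345 probe sets. The platform annotation gave 1 gene symbol for 23521 of them and several for 1814, and 16010 had no annotation entry. A total of 23328 single-symbol probe sets matched the reference gene table (GRCm38.p6), and 0 symbols needed an update. Only single-symbol probe sets were tested as genes, and for the 1082 genes with several such probe sets the one with the highest mean over the 10 arrays was kept, which left 22180 genes. The table carried no detection calls, so no filter on dim genes was applied, and the number of arrays limits the precision.

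Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default settings) on the log2 values. One fit held all 10 arrays and a term for group only, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were 4E-T over IgG, 4E-T over input, IgG over input, and the overlap of the calls of 4E-T over each of the others. The Pearson and Spearman correlations across genes of the differences against input were set beside those of 20 simulations with unchanged groups, since both precipitates share the input arrays. Errors of differences are standard errors of the fit. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

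A total of 23 gene lists were fixed by symbol from general knowledge: proneurogenic factors, radial precursor genes, neuronal genes, ventral forebrain interneuron genes, cell cycle genes, replication-dependent histones, cytosolic ribosomal proteins, translation factors, oxidative phosphorylation, the mitochondrial genome, P-body and decay factors, developmental transcription factors, Zfp zinc fingers, the Notch pathway, Wnt, Shh, FGF and BMP signalling, immediate early and unstable transcripts, erythroid, endothelial, meningeal and mesenchymal, and microglia and macrophage genes, small noncoding RNAs, nuclear long noncoding RNAs, and chemoreceptors (olfactory, vomeronasal and taste). The proneurogenic list follows the subject named in the title of the study, so its result is not independent evidence. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists within a comparison. List medians are given relative to the median of all other genes. The tests, the lists, the alternatives listed last and the rule for naming genes were chosen before the data were examined. That rule took, for each comparison, the 10 highest and 10 lowest log2 differences among called genes whose values did not overlap between the groups. It left out predicted genes, clone names, microRNAs, snoRNAs, scaRNAs and chemoreceptors. The genes reported whatever their test included Eif4enif1, Eif4e, Neurog1, Neurog2, Neurod1, Neurod4, Eomes, Pax6, Sox2, Hes1 and Tubb3, and up to 4 members of each list were taken from the ends of its range in 4E-T over IgG. List members named beside small counts outside that rule were chosen after their values were seen.

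The values showed a pair of arrays, input 1 and 4E-T 1, on a lower scale than the other 8, which is described with the data. A fit with that normalization set as a further term, and a fit of the 8 other arrays, were therefore added after the data and their call counts had been seen. Values called "with the normalization set as a term" come from the first of these. The group-only fit stayed the primary one.

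It was also checked whether equal replicate numbers in the labels mark pairs. Across genes, deviations from the group means of the 4E-T and input arrays with the same number correlated at 0.62, 0.24 and 0.28 in the 10 arrays, which met the pairing criterion of more than 0.1 in each pair. Arrays with different numbers reached 0.27, and among the 8 arrays the same-number correlations of 4E-T and input were 0.044 and 0.0085. The criterion was not met for IgG and input (-0.023, 0.080 and 0.32), and 4E-T and IgG share only the numbers 2 and 3. Call counts with the replicate number as a block had been seen before these correlations were computed, and the criterion was then applied from the correlations alone.

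The gene test was tested on simulated data with 22180 genes and the real design, of which 67 were changed by 0.5, 67 by 1 and 66 by 2 on the log2 scale. For 4E-T over IgG, the group-only fit recovered 0%, 5.97% and 80.3% of these with 0 false calls, and the fit with the normalization set recovered 2.99%, 88.1% and 100.0% with 8 false calls. For 4E-T over input the shares were 0%, 11.9% and 75.8% (0 false calls), and 11.9%, 88.1% and 98.5% (12 false calls) with that term. For IgG over input they were 0%, 8.96% and 77.3% (1 false call), and 8.96%, 86.6% and 98.5% (9 false calls) with that term. The list test was run on 20 simulations of 4E-T over IgG with no changed gene, 460 list tests in all. The group-only fit called 63 of them (13.7%) at the preset correlation and 4 (0.870%) with an estimated correlation, while the fit with the normalization set called 0 at either setting. The group-only list test therefore called too many lists, and list results are given with the normalization set as a term beside it. Apart from the set difference the simulated genes were independent, so the 0 with that term does not cover correlated genes. With the Zfp list raised by 0.5, the group-only fit found it in 20 of 20 simulations at the preset correlation and in 1 with an estimated correlation, and the fit with the normalization set found it in 20 at either setting.

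Alternatives chosen beforehand covered all probe sets in place of genes, the mean of a gene's probe sets, the genes above the median level, median centring, cyclic loess, a repeated quantile normalization, a trend and robust variance, array weights, the groups compared alone, the replicate number as a fixed and as a random block, a minimum log2 difference of 1, leaving out each array in turn, and, for lists, an estimated correlation and limma's fry. Probe sets without a symbol or with several were left out of the comparisons of genes.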

Results

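RNA levels were measured on 10 arrays: 3 of RNA precipitated with 4E-T, 3 of RNA precipitated with control IgG and 4 of total input RNA from embryonic mouse cortex. 4E-T, encoded by Eif4enif1, binds the cap-binding protein eIF4E, represses translation and sits in P-bodies. All values are RMA log2 values, and n is 3 for each precipitate and 4 for input wherever all 10 arrays were fitted. Fits of fewer arrays are named as such. The fit of 8 arrays held only 4E-T 2 and 3 for 4E-T, and inputs 2, 3 and 4. The median over all probe sets was 3.54 on input 1 and 3.52 on 4E-T 1, and between 4.33 and 4.54 on the other 8 arrays. Input 1 and 4E-T 1 also held exactly equal values at 7.52% of the probe sets, against at most 0.138% in any other pair of arrays. The sorted values of this pair differed by 0.0655 on average, and by at least 0.604 from those of any of the other 8, which differed by at most 0.132 among themselves. These 2 arrays are called the lower normalization set, and no IgG array belongs to it. The name is a label, and separate normalization is only a candidate explanation of the lower values. Within a group, arrays correlated across genes at 0.980 to 0.991 for 4E-T, 0.975 to 0.982 for IgG and 0.975 to 0.992 for input.

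**Figure D1:**
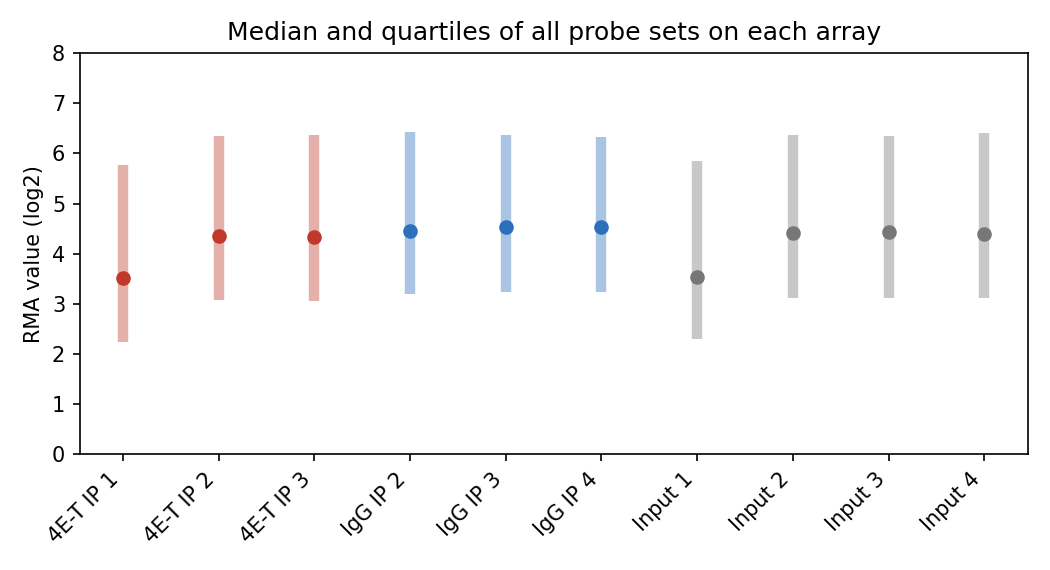
Median (dots) and quartiles (bars) of all probe sets on each of the 10 arrays, by group, in RMA log2 units. Input 1 and 4E-T 1 had medians of 3.54 and 3.52, and the other 8 arrays lay between 4.33 and 4.54.

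Because of that set, the median difference over all genes was -0.19 for 4E-T over IgG, -0.02 for 4E-T over input and 0.20 for IgG over input in the fit with group alone. It was 0.03, 0.04 and 0.03 with the normalization set as a further term (the set term), and 0.02, 0.03 and 0.03 in the 8 other arrays. List medians are therefore given relative to the median of all other genes, and single differences are to be read against these shifts. Within the set itself only a single difference of 4E-T 1 minus input 1 exists, which has no test.

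The comparison of 4E-T with IgG asked which RNAs had a higher relative level in the 4E-T precipitate than in the IgG precipitate. RMA normalizes by quantiles, so the total amount of RNA recovered with each antibody was not compared. Zinc finger genes led the higher side. Zfp759 was higher by 2.37 ± 0.31 (SE, 5.18-fold, adjusted p = 0.00252), Zfp708 by 2.12 ± 0.31, Zfp273 by 1.97 ± 0.27, Zfp599 by 1.94 ± 0.30, Zfp105 by 1.94 ± 0.24 and Zfp870 by 1.90 ± 0.29. Tmem115, which encodes a Golgi membrane protein, was higher by 2.20 ± 0.25 (adjusted p = 0.00183). Zfp472 was higher by 1.99 ± 0.33, Zfp433 by 2.03 ± 0.44 and Nuak2, an AMPK-related kinase gene, by 1.92 ± 0.43 (adjusted p = 0.0118, 0.0435 and 0.0488). The call of Zfp472 was lost without 4E-T 2, 4E-T 3, IgG 3 or IgG 4 (adjusted p from 0.0584 to 0.0715). That of Zfp433 was lost without any 1 of input 2, 3 or 4, 4E-T 2 or 3, or IgG 3 or 4 (from 0.0652 to 0.164), and that of Nuak2 without input 2, 3 or 4, 4E-T 2 or 3, or IgG 2 or 4 (from 0.0647 to 0.179). All 10 were called with the set term, with adjusted p of 0.00665 for Zfp433 and 0.00498 for Nuak2.

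Noncoding RNAs led the lower side. Rny1, a Y RNA bound by the Ro protein, differed by -3.38 ± 0.37 (adjusted p = 0.00154), and Terc, the telomerase RNA, differed by -2.83 ± 0.45. Rpph1, the RNA of RNase P, differed by -2.40 ± 0.45, Vaultrc5, a vault RNA, by -2.10 ± 0.36, Xist by -2.33 ± 0.32 and Miat by -2.21 ± 0.30. The differences were -2.53 ± 0.39 for Ddx5, a DEAD-box helicase gene, -2.31 ± 0.28 for Taf1d, -2.31 ± 0.25 for Spaca6 and -2.12 ± 0.24 for Dleu2, a microRNA host gene. The calls of 3 of these were lost in some fits without 1 array. Ddx5 was lost without IgG 3 (adjusted p = 0.0516), Vaultrc5 without IgG 2 or IgG 4 (0.0676 and 0.0565), and Rpph1 without 4E-T 2 or IgG 2, 3 or 4 (from 0.0686 to 0.112). Over all fits without 1 array the differences stayed between -2.77 and -2.05 for Ddx5, -2.27 and -1.81 for Vaultrc5, and -2.82 and -2.07 for Rpph1. The set term left all 10 called, with differences from -1.75 for Vaultrc5 to -3.06 for Rny1.

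In all, limma called 299 genes, 157 higher and 142 lower in 4E-T than in IgG, and 2814 had an unadjusted p under 0.05. With the set term 2326 were called (1678 higher, 648 lower), and in the 8 arrays alone 1911 (1395 higher, 516 lower). All 299 calls were shared, in the same direction, with both. Median centring of the arrays gave 1095 higher and 415 lower, so that 72.5% of the calls were higher against 52.5% in the fit with group alone. Without 4E-T 1 there were 266 higher and 92 lower (74.3% higher). The count moved to 672 without input 1, 152 without input 2, 160 without input 3, 108 without 4E-T 2, 114 without 4E-T 3, 126 without IgG 2, 90 without IgG 3 and 116 without IgG 4. The groups did not overlap at 1557 genes on the higher side (7.02%) and 3213 on the lower side (14.5%). All 157 and 142 calls were among them. Chance gives 10% for 3 against 3, both sides together, if all arrays can be exchanged. The lower values on 4E-T 1 break that condition, so neither share is to be read against the 10%. The classes left out of the naming made up 7 of the higher and 78 of the lower calls. Of the 18961 genes annotated as protein coding 156 were higher and 47 lower, and of the 1926 long noncoding RNAs 0 and 31. Of the 80 snoRNAs 0 were higher and 30 lower, and of the 478 microRNA genes 1 and 8.

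Zfp zinc finger genes stood out as a group. Of 362 measured, 28 were higher and 0 lower in 4E-T than in IgG, and 62 and 7 adjusted over the list alone. In the fit with the set term 113 were higher and 8 lower, 144 and 15 adjusted over the list alone. The list median was 0.41 above that of the other genes (camera adjusted p = 3.20e-17, and adjusted p = 0.752 with an estimated correlation). It was 0.37 with the set term (7.68e-13, and adjusted p = 0.0101 with an estimated correlation). Zfp932 and Zfp457 lay at the lower end, at -1.37 ± 0.38 and -1.59 ± 0.38. They were not called with group alone, and were called with the set term (adjusted p = 0.0278 and 0.0228) and without input 1 (0.0444 and 0.0205). The camera test with group alone called 13.7% of lists in simulations without any change. List calls below are therefore read with the set term, which called none there. Those simulations drew genes independently apart from the set difference, which that term removes. They do not show that its calls at the preset correlation hold for correlated genes, so values with an estimated correlation are given as well.

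Lists of signalling genes and short-lived transcripts were called higher too. Of 33 immediate early and unstable transcripts, 2 were higher (Klf10, 1.46 ± 0.23, and Ccn1, 1.37 ± 0.28), 3 adjusted over the list alone, and 13 with the set term. Nfkbia (-0.50 ± 0.30) and Dusp6 (-0.67 ± 0.32) were at the lower end and were not called. The list median was 0.32 (adjusted p = 9.17e-05, adjusted p = 0.752 with an estimated correlation) and 0.36 with the set term (2.03e-05, adjusted p = 0.0101 with an estimated correlation). Of 48 genes of Wnt, Shh, FGF and BMP signalling, Axin2 was higher (1.36 ± 0.25), with 5 higher and 1 lower adjusted over the list alone and 16 and 1 with the set term. There Fzd8 reached 1.33 ± 0.31, from 1.25 ± 0.32 without that term, and Fzd3 was the gene that was lower (-0.63 ± 0.13). Its median was 0.33 (3.34e-06, adjusted p = 0.752 with an estimated correlation) and 0.34 with the set term (2.03e-05, adjusted p = 0.0101 with an estimated correlation). Smad5 (-0.60 ± 0.28) was not called. The call of Klf10 was lost without IgG 3 (adjusted p = 0.0632) and that of Axin2 without 4E-T 2, IgG 3 or IgG 4 (from 0.0578 to 0.0991). That of Ccn1 was lost without input 2 or 3, 4E-T 2 or 3, or IgG 2, 3 or 4 (from 0.0523 to 0.136).

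Notch pathway and radial precursor genes had few calls with group alone. Of 33 Notch genes, Hey2 was higher (1.47 ± 0.32) and Mib1, a ubiquitin ligase gene, lower (-1.07 ± 0.20), with 5 and 1 adjusted over the list alone and 12 and 1 with the set term. The median was 0.37 (adjusted p = 8.83e-05, adjusted p = 0.752 with an estimated correlation) and 0.35 with the set term (3.29e-04, adjusted p = 0.0452 with an estimated correlation). Hes5, a Notch effector, was at 1.46 ± 0.38 (adjusted p = 0.0886), was called at 1.85 ± 0.17 with the set term (1.61e-04), and was called without input 1 (0.00845) or 4E-T 1 (0.0461). Notch3 (-0.73 ± 0.27) was not called. Hey2 lost its call without 4E-T 1 or 2, IgG 2, 3 or 4, or input 2, 3 or 4 (adjusted p from 0.0577 to 0.183), and Mib1 without 4E-T 2 or 3 or IgG 2, 3 or 4 (from 0.0715 to 0.0906). Of 34 radial precursor genes limma called 0 with group alone (unadjusted p under 0.05 in 11 higher and 2 lower), 8 higher and 1 lower adjusted over the list alone, and 11 and 2 with the set term. The 2 lower ones were Ccnd2 and Ddah1 (-0.59 ± 0.16 and -0.57 ± 0.15), and Ccnd1 was higher there (1.52 ± 0.39). The radial median was 0.48 (1.25e-06, adjusted p = 0.752 with an estimated correlation), and with the set term 0.30 (9.03e-04, adjusted p = 0.114 with an estimated correlation).

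The proneurogenic factors, which the title of the study names as the subject, are not an independent test. Of 24, limma called 0 with group alone (unadjusted p under 0.05 in 2 higher and 2 lower), 1 higher adjusted over the list alone, and 7 higher with the set term (Dll1, Neurod4, Neurod1, Nhlh2, Gadd45g, Neurog1 and Neurog2), 8 higher and 1 lower adjusted over the list alone. Dll1 was at 0.93 ± 0.21 (adjusted p = 0.0565), and at 0.97 ± 0.16 with the set term (0.00335), and was called without input 1 (0.0279). Neurog2 was at 0.47 ± 0.29 (0.539) and at 0.72 ± 0.16 with the set term (0.0136). Neurog1 was at 0.41 ± 0.33 and 0.73 ± 0.16 (0.624 and 0.0142), Neurod1 at 0.48 ± 0.38 and 0.86 ± 0.17 (0.621 and 0.00749), and Neurod4 at 0.56 ± 0.36 and 0.89 ± 0.21 (0.552 and 0.0186). Ebf2 (0.75 ± 0.48, and 0.20 without IgG 4), Sox11 (-0.66 ± 0.30) and Myt1 (-0.76 ± 0.32) were not called in either fit. The median was 0.22 (adjusted p = 0.0315, adjusted p = 0.806 with an estimated correlation) and 0.24 with the set term (0.0168, adjusted p = 0.176 with an estimated correlation). The list call was lost without 4E-T 1 (0.0584), IgG 2 (0.0549) or IgG 4 (0.0625).

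Among the other genes reported whatever their test, Sox2 was at 0.96 ± 0.23 (adjusted p = 0.0728) and at 1.06 ± 0.17 with the set term (0.00298), and was called without input 1 (0.0271). Hes1 was at 0.51 ± 0.26 (0.456) and at 0.68 ± 0.17 with the set term (0.0229). Eif4enif1 (0.40 ± 0.22), Eif4e (-0.23 ± 0.24), Eomes (-0.02 ± 0.23), Pax6 (0.21 ± 0.21) and Tubb3 (0.53 ± 0.24) were called in neither fit.

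**Figure D2:**
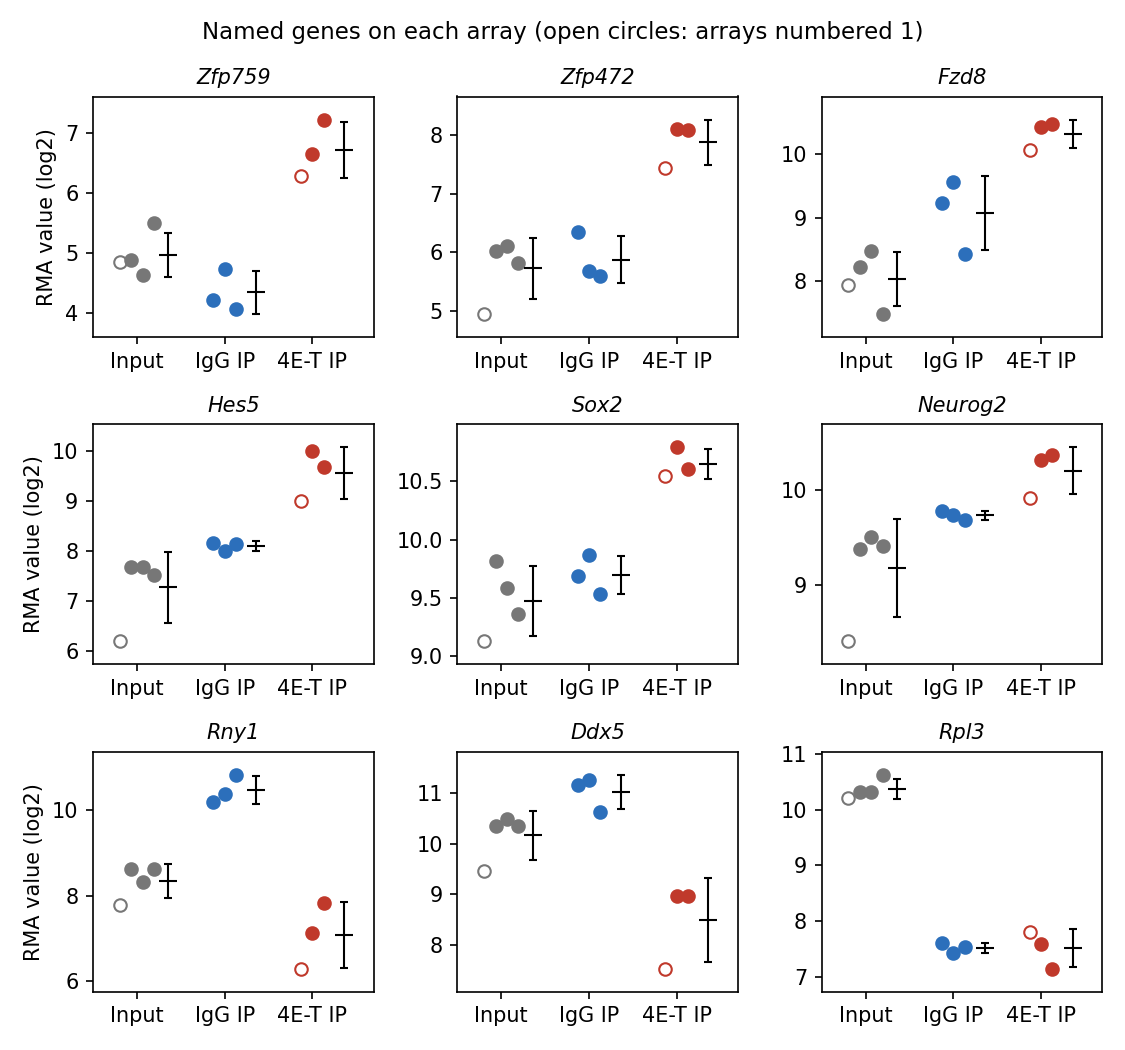
RMA log2 values per array of Zfp759, Zfp472, Fzd8, Hes5, Sox2, Neurog2, Rny1, Ddx5 and Rpl3 in input (n = 4), IgG (n = 3) and 4E-T (n = 3) samples. Open circles are the arrays numbered 1, and black marks are the mean and SD, for Neurog2 9.17 and 0.52 in input, 9.73 and 0.05 in IgG, and 10.21 and 0.25 in 4E-T.

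Several lists were called lower in 4E-T than in IgG. Of 571 small noncoding RNAs 44 were lower and 1 higher, 78 and 1 adjusted over the list alone, and 80 and 2 with the set term. Snord89 was at -4.92 ± 0.39 and Scarna6 at -4.02 ± 0.37, and the higher one was Mir3098 at 2.54 ± 0.49, a call lost without 4E-T 2 or 3 or IgG 2 or 3 (adjusted p from 0.106 to 0.110). Mir1945 (0.60 ± 0.33) was not called. The median was -0.25 (1.01e-13, adjusted p = 0.752 with an estimated correlation), and -0.24 with the set term (4.48e-13, adjusted p = 4.14e-05 with an estimated correlation). Of 16 nuclear long noncoding RNAs, Xist, Miat, Rian and Snhg12 were lower and 0 higher, 8 adjusted over the list alone and 8 with the set term. Dlx6os1 (0.04 ± 0.38) and Neat1 (-0.22 ± 0.28) were not called. The median was -0.59 (2.25e-08, adjusted p = 0.752 with an estimated correlation), and -0.58 with the set term (2.29e-09, adjusted p = 0.0101 with an estimated correlation). Of the 10 genes of the mitochondrial genome ND2 was lower (-1.15 ± 0.26), all 10 adjusted over the list alone, and 9 with the set term, among them ND4L (-0.81 ± 0.14) and ND5 (-0.49 ± 0.13) but not ND3 (-0.40 ± 0.13). The median was -0.58 (1.59e-07, adjusted p = 0.752 with an estimated correlation), and -0.62 with the set term (5.36e-10, adjusted p = 0.131 with an estimated correlation). The call of ND2 was lost without any 1 array other than input 1 (adjusted p from 0.0723 to 0.187).

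Of 1427 chemoreceptor genes Olfr1564 (-2.42 ± 0.31), Vmn1r80 (-1.43 ± 0.32) and Vmn2r38 were lower than in IgG, 1 adjusted over the list alone, with 16 lower and 2 higher with the set term. Their median was -0.15 (adjusted p = 1.43e-05, adjusted p = 0.806 with an estimated correlation) and -0.15 with the set term (2.38e-05, adjusted p = 0.0145 with an estimated correlation). Olfr801 (1.41 ± 0.91, and -0.05 without 4E-T 3) and Olfr403 (0.59 ± 0.24) were not called. Vmn1r80 lost its call without 4E-T 1, 2 or 3, IgG 2, 3 or 4, or input 2 or 4 (from 0.0769 to 0.206).

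A further 5 lists were called with group alone. Of 37 cell cycle genes, Cdc6 (1.41 ± 0.31) and Aurkb (1.14 ± 0.25) were higher, 3 adjusted over the list alone, and 8 higher and 1 lower with the set term, with Kif11 (-0.46 ± 0.22) and Ccnb2 (-0.54 ± 0.22) at the lower end and not called. The cell cycle median was 0.46 (adjusted p = 2.66e-06, adjusted p = 0.752 with an estimated correlation) and 0.30 with the set term (0.0353, adjusted p = 0.759 with an estimated correlation), and 0.16 and not called with the replicate block (0.265). Of 52 P-body and decay factors Cnot4 was higher (1.16 ± 0.22) and Pum2 lower (-1.07 ± 0.23), 3 and 1 adjusted over the list alone, and 11 and 3 with the set term, among them Zfp36l1 (1.18 ± 0.17) and Pan3 (-0.56 ± 0.14). Their median was 0.27 (0.0293, adjusted p = 0.848 with an estimated correlation; without IgG 4 0.20 and 0.102) and 0.16 with the set term (0.0379, adjusted p = 0.245 with an estimated correlation), and 0.14 and not called with the replicate block (0.0804). Of 314 developmental transcription factors Hey2, Klf10, Otx2 and Bhlhe40 were higher and 0 lower, 4 and 0 adjusted over the list alone, and 40 and 1 with the set term, where Nfia was the gene that was lower (-0.72 ± 0.17) and Hoxa10 was not called (-0.46 ± 0.16). Their median was 0.12 (0.0130, adjusted p = 0.870 with an estimated correlation) and 0.14 with the set term (0.00193, adjusted p = 0.114 with an estimated correlation). Of 18 endothelial genes Kdr was higher (1.35 ± 0.27), 1 adjusted over the list alone, and 3 with the set term, with a median of 0.23 (0.0315, adjusted p = 0.806 with an estimated correlation) and 0.28 with the set term (0.0168, adjusted p = 0.143 with an estimated correlation). That list lost its call without 4E-T 2 (0.119) or IgG 2 (0.0850). Of 10 erythroid genes limma called 0 (unadjusted p under 0.05 in 2, both higher), and Tspan33 (0.89 ± 0.25) led, with 1 adjusted over the list alone and 2 with the set term. The erythroid median was 0.27 (0.0374, adjusted p = 0.752 with an estimated correlation), was not called without 4E-T 1 (0.0608) or IgG 4 (0.208), was 0.14 with the set term (0.0713) and 0.05 with the replicate block (0.336).

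Of the single calls in these lists, several were lost when 1 array was left out, while their differences kept their sign (for Pum2 from -1.16 to -0.97). Cdc6 lost its call without input 2, 3 or 4, 4E-T 2 or 3, or IgG 3 or 4 (adjusted p from 0.0562 to 0.192), and Cnot4 without input 2 or 3, 4E-T 2 or 3, or IgG 2, 3 or 4 (from 0.0521 to 0.128). Aurkb lost it without input 2 or 3 or any 1 precipitate array (from 0.0635 to 0.171), Kdr without input 2 or 3, 4E-T 2 or 3, or IgG 2, 3 or 4 (from 0.0519 to 0.136), and Pum2 without any 1 array other than input 1 (from 0.0640 to 0.153). All of these were called with the set term.

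The remaining lists were called in neither fit in 4E-T over IgG. Of 66 cytosolic ribosomal protein genes limma called 0 (unadjusted p under 0.05 in 3 higher and 6 lower), 0 adjusted over the list alone, and 3 higher and 4 lower with the set term, where Rpl32 was higher (0.97 ± 0.15), Rpl6 lower (-0.84 ± 0.22), and neither Rpl7l1 nor Rps20 was called. Their median was 0.04 and their mean 0.02 while the test pointed down (adjusted p = 0.765). With the set term the median was -0.09 (0.101), and in the 8 arrays it was -0.13 and called (0.00919). Of 82 oxidative phosphorylation genes limma called 0 (unadjusted p under 0.05 in 4 higher and 2 lower), 0 adjusted over the list alone, and 3 higher and 1 lower with the set term, among them Atp5e (0.99 ± 0.14) and Ndufs8 (0.72 ± 0.18). Their median was 0.18 (0.112), was called higher without 4E-T 2 (7.56e-04) or 4E-T 3 (0.00450), and with the set term was 0.02 with a mean of -0.01. Of 72 translation factors Eif4a1 (-1.32 ± 0.25) and Eif4a2 (-1.31 ± 0.25) were lower, 2 adjusted over the list alone, and 7 higher and 6 lower with the set term, Paip2b among the higher (1.00 ± 0.20). The calls were lost without input 2, 4E-T 2 or 3, or IgG 2, 3 or 4, and for Eif4a2 also without input 3 (adjusted p from 0.0512 to 0.112 for Eif4a1 and from 0.0521 to 0.124 for Eif4a2). The median of the translation factors was 0.08 (0.677).

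Of 25 replication-dependent histones limma called 0 (unadjusted p under 0.05 in 2 higher and 4 lower), 0 adjusted over the list alone and 0 with the set term, with H2ac21 (1.06 ± 0.39, and 0.51 without 4E-T 1) and H2bc14 (-1.01 ± 0.33) at the ends. Their median was 0.13 (adjusted p = 0.692), -0.06 with the set term (0.371), and -0.26 and called lower in the 8 arrays (0.0226) and without 4E-T 1 (0.0200). Of 34 neuronal genes Dcx was lower (-1.23 ± 0.26), 1 adjusted over the list alone, and 3 with the set term (Dcx, Gria2 and Cplx2). That call was lost without input 2 or 3 or any 1 precipitate array (from 0.0639 to 0.163). The neuronal median was 0.04, the mean -0.05 and the test pointed down (0.620). Of 17 ventral forebrain interneuron genes limma called 0 (unadjusted p under 0.05 in 2, both higher), 0 adjusted over the list alone, and Gad2 (1.16 ± 0.23) and Gsx2 (1.12 ± 0.33) with the set term. Their median was 0.28 (0.101, and 0.0310 without IgG 3). Of 20 meningeal and mesenchymal genes limma called 0 (unadjusted p under 0.05 in 2, both lower), 0 adjusted over the list alone, and Foxc1 (1.42 ± 0.15) with the set term, with a median of 0.02, a mean of -0.01 and a test that pointed up (0.765). Of 18 microglia and macrophage genes limma called 0 in either fit (unadjusted p under 0.05 in 4, all lower, with group alone), 0 adjusted over the list alone, with a median of -0.14 (0.0543, and 0.0498, 0.0390, 0.0493, 0.0328 and 0.0264 without input 1, input 4, 4E-T 1, 4E-T 2 and IgG 2).

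The comparison of 4E-T with input asked how the recovered RNA differed from the total RNA of the tissue. Fzd8, a Wnt receptor gene, was higher by 2.29 ± 0.30 (4.89-fold, adjusted p = 0.00203), and Hes5 by 2.29 ± 0.36 (4.88-fold, 0.00411). Pcdh18, a protocadherin gene, was higher by 2.08 ± 0.21 and Ccn1, a matricellular gene induced by growth factors, by 1.99 ± 0.26. Zfp472 (2.14 ± 0.31), Zfp433 (2.14 ± 0.41), Zfp958 (2.10 ± 0.19), Zfp119b (2.02 ± 0.34), Zfp786 (1.95 ± 0.28) and Zfp619 (1.94 ± 0.27) made up the rest of the 10 highest. Rpph1 (-3.17 ± 0.42), the ribosomal protein genes Rpl3 (-2.86 ± 0.22), Rplp0 (-2.63 ± 0.24), Rps27 (-1.97 ± 0.28 with the set term) and Rpl6l (-1.93 ± 0.24), and Terc (-2.16 ± 0.42) were among the 10 lowest. The others were Lgals1, a galectin gene (-2.24 ± 0.36), Snhg7, a snoRNA host gene (-2.10 ± 0.24), Mpc1, a pyruvate carrier gene (-2.03 ± 0.37), and Pcp4 (-1.96 ± 0.23 with the set term). Zfp433 lost its call without 4E-T 2 (adjusted p = 0.0601) or 4E-T 3 (0.0532), and Mpc1 without 4E-T 2 (0.0524). All 20 were called with the set term. In the pair numbered 1 the difference was 2.12 for Fzd8, 2.80 for Hes5, -2.41 for Rpl3 and -1.92 for Rplp0.

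Among the genes reported whatever their test, Sox2 was higher than in input by 1.18 ± 0.22 (adjusted p = 0.00855, and 0.0563 without 4E-T 2). Neurog2 was higher by 1.04 ± 0.27 (0.0410) and Hes1 by 0.95 ± 0.24 (0.0363). Both calls were lost without any 1 array other than input 1 and 4E-T 1 (from 0.0609 to 0.174 for Neurog2 and from 0.0551 to 0.153 for Hes1), and both held with the set term (2.93e-04 and 6.68e-04). Neurod4 (1.17 ± 0.34, 0.0634), Eif4enif1 (0.69 ± 0.20, 0.0669), Neurog1 (0.58 ± 0.31, 0.426) and Neurod1 (0.58 ± 0.36, 0.537) did not pass. They passed with the set term (6.35e-04, 0.00337, 0.00661 and 0.00685) and with the replicate number as a block (6.83e-04, 0.00424, 0.0151 and 0.00533), and Neurod4 and Eif4enif1 also without 4E-T 1 (0.0103 and 0.0462). Eomes (0.28 ± 0.22), Pax6 (0.38 ± 0.20), Eif4e (-0.17 ± 0.23) and Tubb3 (-0.22 ± 0.22) passed in none of these fits. In the pair numbered 1 the differences were 1.42 for Sox2, 1.52 for Neurog2, 1.47 for Hes1, 1.03 for Neurog1, 0.88 for Neurod1 and 1.06 for Neurod4.

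In all, limma called 1361 genes in 4E-T over input, 568 higher and 793 lower (41.7% higher), and 3726 had an unadjusted p under 0.05. With the set term 4274 were called (2309 and 1965), in the 8 arrays 3567 (1969 and 1598), and with the replicate number as a block 4510 (2411 and 2099). Of the 1361 calls all were shared in the same direction with the set term and 1355 with the 8 arrays. Median centring gave 1427 higher and 1235 lower (53.6% higher). The balance moved most with the arrays of the lower set. Without 4E-T 1 there were 1298 higher and 707 lower (64.7% higher), and without input 1 557 and 1376 (28.8% higher). Either omission leaves the lower set in only 1 of the groups compared. In the 8 arrays 55.2% were higher, and without any other single array from 31.8% to 42.7%. The count was 615 without input 2, 639 without input 3, 742 without input 4, 371 without 4E-T 2 and 421 without 4E-T 3. Of the 1969 genes higher in the 8 arrays, 1834 (93.1%) were also higher in 4E-T 1 than in input 1, and of the 1598 lower ones 1505 (94.2%) were also lower. The groups did not overlap at 1430 genes on the higher side (6.45%) and 1873 on the lower side (8.44%). Of the calls 564 and 789 were among them. Chance gives 5.71% for 3 against 4, both sides together, if all arrays can be exchanged. The lower values on 4E-T 1 and input 1 break that condition as well.

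Lists of genes for ribosomal proteins and respiration were called lower in 4E-T than in input. Of 82 oxidative phosphorylation genes 41 were lower and 0 higher, 61 adjusted over the list alone and 62 with the set term. Their median was -0.73 (adjusted p = 3.24e-34, adjusted p = 0.162 with an estimated correlation) and -0.79 with the set term (4.47e-31, adjusted p = 0.0310 with an estimated correlation). Of 66 cytosolic ribosomal protein genes 25 were lower and 0 higher, 39 adjusted over the list alone and 41 with the set term. Their median was -0.61 (3.04e-26, adjusted p = 0.162 with an estimated correlation) and -0.65 with the set term (5.72e-24, adjusted p = 0.0143 with an estimated correlation). Of 72 translation factors 12 were lower, 21 lower and 4 higher adjusted over the list alone, and 24 and 8 with the set term, with a median of -0.22 (1.68e-06, adjusted p = 0.514 with an estimated correlation) and -0.26 with the set term (7.44e-07, adjusted p = 0.00609 with an estimated correlation). Of 25 replication-dependent histones H4c9 was lower, 1 adjusted over the list alone, and 9 lower and H2bc21 higher with the set term, with a median of -0.50 (2.43e-06, adjusted p = 0.514 with an estimated correlation) and -0.54 with the set term (7.02e-06, adjusted p = 0.189 with an estimated correlation). The histone median depended on 4E-T 1: it was -0.96 without that array and -0.99 in the 8 arrays, where 15 were lower and 1 higher, 17 and 1 adjusted over the list alone.

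The lists of Zfp genes and signalling genes were called higher in 4E-T than in input as well. Of the Zfp genes 91 were higher and 2 lower, 132 and 6 adjusted over the list alone and 177 and 14 with the set term. Their median was 0.50 (adjusted p = 2.77e-24, adjusted p = 0.514 with an estimated correlation) and 0.51 with the set term (2.36e-19, adjusted p = 0.00609 with an estimated correlation). Of the Wnt, Shh, FGF and BMP genes 9 were higher and 0 lower, 15 adjusted over the list alone and 23 with the set term, with a median of 0.42 (2.67e-10, adjusted p = 0.514 with an estimated correlation) and 0.43 with the set term (2.18e-09, adjusted p = 0.00609 with an estimated correlation). Of the Notch genes Hes5, Jag1, Dll1, Maml2 and Hes1 were higher, 10 adjusted over the list alone and 14 with the set term (median 0.34 and 2.35e-06, adjusted p = 0.514 with an estimated correlation; with the set term 0.37 and 8.69e-06, adjusted p = 0.0194 with an estimated correlation). Of the immediate early transcripts Ccn1, Jun, Klf10 and Klf6 were higher and Gadd45g and Jund lower, 4 and 2 adjusted over the list alone, and 15 and 2 with the set term (median 0.38 and 2.03e-05, adjusted p = 0.514 with an estimated correlation; with the set term 0.42 and 8.69e-06, adjusted p = 0.00876 with an estimated correlation). Of the proneurogenic factors Dll1 (1.39 ± 0.20), Nhlh2 and Neurog2 were higher and Gadd45g lower (-0.95 ± 0.19 with the set term), 4 and 1 adjusted over the list alone, and 11 and 1 with the set term. Their median was 0.60 (2.02e-05, adjusted p = 0.514 with an estimated correlation) and 0.60 with the set term (1.04e-05, adjusted p = 0.0306 with an estimated correlation), and the same reservation about the title holds.

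Of the radial precursor genes 6 were higher than in input (Hes5, Sox2, Sox1, Hes1, Nes and Emx2) and Vim was lower, 12 and 3 adjusted over the list alone and 10 and 4 with the set term. Their median was 0.33 (adjusted p = 8.58e-04, adjusted p = 0.514 with an estimated correlation, and 0.102 without 4E-T 1), and 0.33 with the set term (0.0102, adjusted p = 0.169 with an estimated correlation). The lists of ventral forebrain interneuron genes (median 0.28, adjusted p = 0.0424) and of cell cycle genes (0.14, 0.0107) were called with group alone (adjusted p = 0.720 with an estimated correlation for both). They were called neither with the set term (0.0808 and 0.134) nor with the replicate block (0.0943 and 0.614). The first was also lost without 4E-T 1 (0.119), input 2 (0.0564), 4E-T 3 (0.0639) or input 4 (0.108), and the second without 4E-T 1 (0.415) or input 4 (0.350).

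The lists of noncoding RNAs, the mitochondrial genome and microglia markers were called lower in 4E-T than in input, the last 2 in neither fit with an estimated correlation. Of 571 small noncoding RNAs 20 were lower and 1 higher, 14 and 0 adjusted over the list alone and 51 and 7 with the set term. Their median was -0.08 (adjusted p = 0.0150, adjusted p = 0.868 with an estimated correlation) and -0.07 with the set term (0.0185, adjusted p = 0.00609 with an estimated correlation). Of 16 nuclear long noncoding RNAs Snhg12, Miat and Rian were lower, 5 adjusted over the list alone, and 8 lower and Peg13 higher with the set term. Their median was -0.58 (1.71e-04, adjusted p = 0.514 with an estimated correlation) and -0.57 with the set term (4.55e-05, adjusted p = 0.0306 with an estimated correlation). Of the 10 genes of the mitochondrial genome limma called 0 (unadjusted p under 0.05 in 3, all lower), 1 lower adjusted over the list alone and 6 with the set term, with a median of -0.45 (4.16e-04, adjusted p = 0.514 with an estimated correlation) and -0.46 with the set term (2.56e-05, adjusted p = 0.238 with an estimated correlation). Of 18 microglia and macrophage genes Tyrobp was lower, 1 adjusted over the list alone, and with the set term Tyrobp, Cd68, C1qb, Fcer1g and Ctss were lower and Cx3cr1 higher. Their median was -0.37 (0.00486, adjusted p = 0.656 with an estimated correlation) and -0.38 with the set term (0.00595, adjusted p = 0.169 with an estimated correlation).

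The P-body and developmental lists were called higher than in input, the P-body list in neither fit with an estimated correlation. Of 52 P-body and decay factors 7 were higher and Lsm4 and Lsm5 lower, 8 and 3 adjusted over the list alone, and 19 higher and Lsm4, Lsm5 and Lsm1 lower with the set term. Their median was 0.20 (adjusted p = 0.00729, adjusted p = 0.720 with an estimated correlation) and 0.20 with the set term (0.00435, adjusted p = 0.121 with an estimated correlation). Of 314 developmental transcription factors 21 were higher and 0 lower, 24 and 0 adjusted over the list alone, and 64 higher and Pbx4, Hoxa10 and Ascl4 lower with the set term. Their median was 0.12 (1.77e-05, adjusted p = 0.720 with an estimated correlation) and 0.13 with the set term (1.04e-05, adjusted p = 0.0306 with an estimated correlation). The neuronal, erythroid, endothelial, meningeal and chemoreceptor lists were called in neither fit, and the neuronal one was called lower without input 2 (-0.24, adjusted p = 0.0326).

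A gene that was higher in 4E-T than in both IgG and input met the usual criterion for recovery by an antibody, and 94 genes did, among them Zfp433, Zfp472 and Ccn1. Independent lists of these sizes would share 4.02 genes. By the same criterion 56 genes were higher in IgG than in both 4E-T and input. Genes lower in 4E-T than in both numbered 46, where independent lists would share 5.08. With the set term the numbers for 4E-T were 948 higher (174.7 if independent) and 265 lower (57.4 if independent), and 302 genes were higher in IgG than in both others. Both comparisons of 4E-T use the same 4E-T arrays, so the values for independent lists are not those without any change. In 20 simulations without any change 0 genes were shared. With no changed gene few calls can arise in either comparison, so that 0 was fixed in advance. How much of the overlap comes from the shared arrays was therefore not shown. The 94 moved to 170 without input 1, 37 without input 2, 39 without input 3, 54 without input 4, 185 without 4E-T 1, 23 without 4E-T 2, 23 without 4E-T 3, 46 without IgG 2, 26 without IgG 3 and 35 without IgG 4.

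The comparison of IgG with input asked how RNA precipitated without the 4E-T antibody differed in composition from total RNA. Rny1 was higher by 2.12 ± 0.34 (4.36-fold, adjusted p = 0.00395) and Xist by 1.72 ± 0.30. Also among the 10 highest were n-R5s136, a 5S ribosomal RNA gene (1.90 ± 0.30), Klhl28 (1.84 ± 0.28), Zfp457 (1.81 ± 0.36), Gabra2, a GABA-A receptor gene (1.65 ± 0.26), Fam126b (1.61 ± 0.43), Slc38a2, an amino acid transporter gene (1.61 ± 0.29), Mtx3 (1.56 ± 0.23) and Trp53inp1 (1.54 ± 0.37). The lowest were S100a6, a calcium-binding protein gene (-2.90 ± 0.46), Rpl3 (-2.85 ± 0.22), Coa3, a cytochrome c oxidase assembly gene (-2.69 ± 0.21), Myl6 (-2.65 ± 0.27) and Rplp0 (-2.53 ± 0.24). Hsd3b6 (-2.39 ± 0.45), Rps7 (-2.36 ± 0.32), Hscb (-2.34 ± 0.23), Tufm, a mitochondrial elongation factor gene (-2.33 ± 0.25), and Crip1 (-2.29 ± 0.32) followed. The calls of Zfp457 were lost without IgG 2 (adjusted p = 0.0680) or IgG 4 (0.0547), of Hsd3b6 without IgG 2 (0.0507), of Trp53inp1 without input 2 or 3 or IgG 2, 3 or 4 (from 0.0576 to 0.138), and of Fam126b without any 1 array other than those numbered 1 (from 0.0531 to 0.184). All 20 were called with the set term. Of Eif4enif1, Eif4e, Neurog1, Neurog2, Neurod1, Neurod4, Eomes, Pax6, Sox2, Hes1 and Tubb3 none was called: Tubb3 came nearest (-0.75 ± 0.22, 0.0732), and was called with the set term (0.0107) and without input 1 (0.0277) or 4E-T 1 (0.0487).

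Several genes named from the lower ends of the lists in 4E-T over IgG were higher in IgG than in input. Both comparisons use the same IgG arrays, so choosing genes low in 4E-T over IgG favours this result. Only genes with a call are listed, so this is no independent evidence. Pum2 (1.33 ± 0.21, adjusted p = 0.00364), Fzd3 (1.36 ± 0.23), Scarna6 (3.09 ± 0.35), Snord89 (4.31 ± 0.36) and Olfr1564 (2.31 ± 0.29) kept their calls without any 1 array. The calls of Mib1 (0.87 ± 0.19) and Dusp6 (1.22 ± 0.30) were lost without input 2 or 3 or IgG 2, 3 or 4 (adjusted p from 0.0573 to 0.0803 and from 0.0516 to 0.169), and that of Vmn1r80 (1.30 ± 0.30) without input 2 or 4 or IgG 2, 3 or 4 (from 0.0589 to 0.131). That of Dcx (0.98 ± 0.24) was lost without input 2 or 3, 4E-T 2, or IgG 2, 3 or 4 (from 0.0549 to 0.159). The call of Nfia (0.95 ± 0.25) was lost without input 1, 2 or 3, 4E-T 2 or 3, or IgG 2, 3 or 4 (from 0.0519 to 0.181), and that of Nfkbia (1.08 ± 0.28) without any 1 input or IgG array or 4E-T 3 (from 0.0555 to 0.159). All were called with the set term.

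Here limma called 1206 genes, 322 higher and 884 lower (26.7% higher), and 3959 had an unadjusted p under 0.05. With the set term 3688 were called (1361 and 2327), and in the 8 arrays 3471 (1259 and 2212), and all 1206 were shared with both in the same direction. Cyclic loess gave 1519 higher and 1870 lower (44.8% higher), and repeated quantile normalization 1686 and 1803 (48.3% higher). Without 4E-T 1 there were 770 higher and 1096 lower (41.3% higher), and without input 1 289 and 1272 (18.5% higher). The count was 1866 without 4E-T 1, 477 without input 2, 497 without input 3, 652 without input 4, 554 without IgG 2, 444 without IgG 3 and 453 without IgG 4. The groups did not overlap at 3126 genes on the higher side (14.1%) and 1825 on the lower side (8.23%). Of the calls 322 and 881 were among them. Chance gives 5.71%, both sides together, if all arrays can be exchanged, a condition that the lower values on input 1 break.

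The ribosomal and respiratory lists were called lower in IgG than in input too. Of 82 oxidative phosphorylation genes 45 were lower and 0 higher, 56 adjusted over the list alone and 61 with the set term, with a median of -1.02 (adjusted p = 8.64e-40, adjusted p = 0.153 with an estimated correlation) and -0.85 with the set term (7.66e-29, adjusted p = 0.0798 with an estimated correlation). Of 66 cytosolic ribosomal protein genes 20 were lower and 0 higher, 36 and 1 adjusted over the list alone and 41 and 1 with the set term, with a median of -0.78 (8.01e-25, adjusted p = 0.183 with an estimated correlation) and -0.69 with the set term (8.98e-19, adjusted p = 0.0517 with an estimated correlation). Small noncoding RNAs were higher in IgG than in input: 32 were higher and 1 lower, 33 and 1 adjusted over the list alone and 63 and 8 with the set term. Their median was 0.16 (3.79e-06, adjusted p = 0.903 with an estimated correlation) and 0.16 with the set term (1.05e-05, adjusted p = 6.13e-04 with an estimated correlation). Of the Zfp genes 15 were higher and 4 lower, 15 and 4 adjusted over the list alone, and 61 and 22 with the set term. Their median was 0.05 (0.0781, and 0.0398 without input 1) and 0.06 with the set term (0.0249, adjusted p = 0.265 with an estimated correlation). The proneurogenic median was 0.26 (0.0553) and 0.28 with the set term (0.0194, adjusted p = 0.236 with an estimated correlation), with Btg2 higher and Gadd45g lower, 5 and 2 adjusted over the list alone, and 6 and 2 with the set term. That list was also called without input 1 (0.0393), input 2 (0.0457), input 3 (0.0384) or IgG 4 (0.0389).

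Further lists were called in IgG over input. Of 25 replication-dependent histones H1f2, H2bc12, H2ac21 and H4c9 were lower, 8 adjusted over the list alone and 8 with the set term, with a median of -0.55 (adjusted p = 1.48e-06, adjusted p = 0.554 with an estimated correlation) and -0.48 with the set term (5.66e-04, adjusted p = 0.417 with an estimated correlation). Of 72 translation factors 16 were lower and 0 higher, 17 and 2 adjusted over the list alone and 26 and 5 with the set term, with a median of -0.37 (9.14e-07, adjusted p = 0.903 with an estimated correlation) and -0.32 with the set term (2.31e-05, adjusted p = 0.0235 with an estimated correlation). Of 1427 chemoreceptor genes 6 were higher and 0 lower, 1 adjusted over the list alone and 47 and 5 with the set term, with a median of 0.10 (7.79e-04, adjusted p = 0.903 with an estimated correlation) and 0.10 with the set term (0.00113, adjusted p = 0.0586 with an estimated correlation). With group alone 114 chemoreceptor genes had an unadjusted p under 0.05 on the higher side and 1 on the lower side. Background on dim probe sets was not separated from RNA here either. Not called with group alone but called with the set term were the nuclear long noncoding RNAs (0.19, 0.0447, adjusted p = 0.265 with an estimated correlation), the mitochondrial genome (0.18, 0.0194, adjusted p = 0.602 with an estimated correlation), the Wnt, Shh, FGF and BMP genes (0.09, 0.0390, adjusted p = 0.112 with an estimated correlation) and, on the lower side, the endothelial genes (-0.21, 0.0256, adjusted p = 0.236 with an estimated correlation). The nuclear list was also called without input 1 (0.0393), input 2 (0.0455) or IgG 4 (0.0389), and the mitochondrial one without input 2 (0.0455). The cell cycle list was called lower without IgG 2 (0.00277), input 3 (0.0384) or input 4 (8.89e-04), and in neither fit of all arrays.

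**Figure D3:**
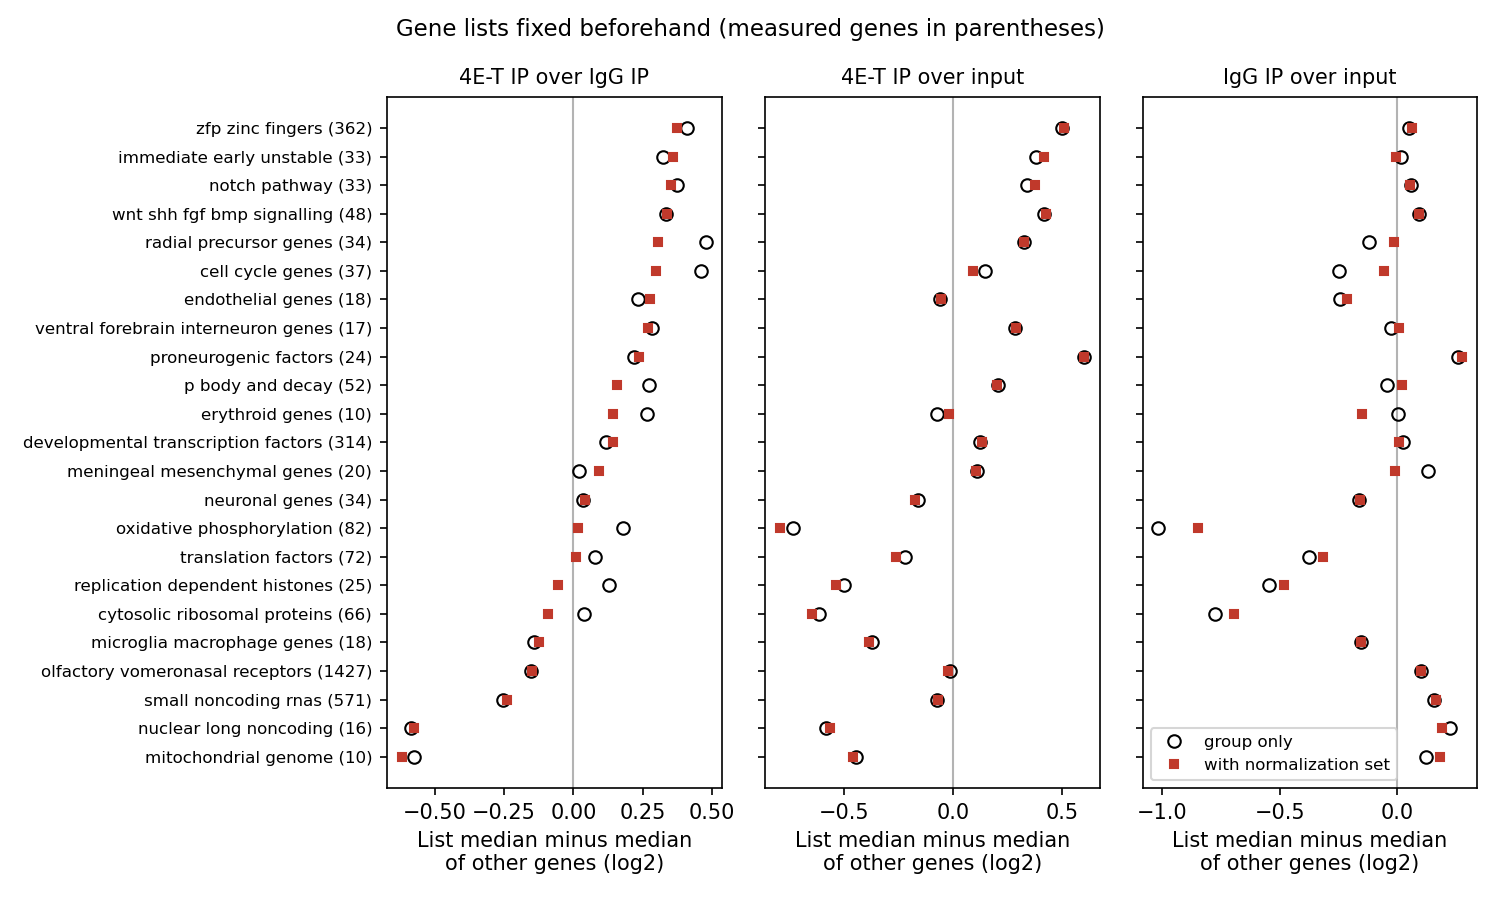
Median log2 difference of each gene list minus the median of all other genes in the 3 comparisons, with group alone (open circles) and with the normalization set as a term (red squares). Oxidative phosphorylation lay at -0.73 in 4E-T over input and -1.02 in IgG over input, and Zfp zinc fingers at 0.41 in 4E-T over IgG and 0.50 in 4E-T over input (open circles).

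Across genes, the differences of 4E-T over input and of IgG over input correlated at r = 0.527 and rho = 0.445, and genes are not independent replicates. Both share the input arrays. Simulations of unchanged groups in the same design, with the input arrays simulated as well, gave r = 0.429 and rho = 0.410. The simulated arrays were drawn independently. A shift shared by the arrays of the lower normalization set was therefore not part of these values for the fit with group alone. The covariance was 0.109 against 0.0371 in the simulations, a difference of 0.0716. In the fit with the set term r was 0.550 against 0.386, and the covariance 0.107 against 0.0128, a difference of 0.0947. With the 4 inputs split between the comparisons, r lay between 0.279 and 0.492 and rho between 0.148 and 0.379. The place of input 1 set this range. With input 1 on the side of 4E-T, r was 0.471 to 0.492, and on the side of IgG it was 0.279 to 0.301.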

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

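All tests of the lower values on the arrays numbered 1 were chosen after those values were seen.

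Among the 4 input arrays, input 1 lay far from the others. For the array medians the gap from input 1 to its nearest neighbour made up 0.954 of the whole range of the group. The same ratio was taken for 143 named genes, and in 22 of them 1 input array stood apart, where chance gives about 1 in 20 groups (5%). All 143 genes were read on the same 4 arrays and many were named for their differences. They are therefore not independent tries against that 5%. Together with the medians, the 22 genes made up 23 items, and in 19 of them the array that stood apart was input 1. It was the lowest of the group for Terc (0.934), Ddx5 (0.872), Rpph1 (0.876), Vaultrc5 (0.908), Hes5 (0.893), Fam126b (0.911), Slc38a2 (0.845), Neurog1 (0.856), Neurog2 (0.893), Neurod1 (0.921) and Hes1 (0.937). It was also the lowest for Rps20 (0.852), Eif4a1 (0.837), Hoxa10 (0.958), Fzd3 (0.840), Nfkbia (0.850), Epb42 (0.876) and Fli1 (0.889). The remaining ones were Zfp599 (0.842), highest on input 4, Ebf2 (0.867), lowest on input 4, n-R5s136 (0.866), highest on input 3, and Dlx6os1 (0.833), highest on input 3.

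A candidate explanation is that the authors normalized input 1 and 4E-T 1 apart from the other 8 arrays. RMA gives arrays normalized together nearly the same sorted values. With each array centred on its median, so that the lower level itself did not decide, the distance between the sorted values of this pair was 0.313 times the smallest distance from either of them to any of the other 8, which the explanation needs. Such a set shifts every comparison of groups that hold different shares of it, and IgG has none of it. Lower RNA quality in this pair was not tested. The labels give the pair the same replicate number, which could mark a separate preparation, and neither that nor a biological explanation was tested.

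Signal also appeared in probe sets left out of the comparisons of genes. In a fit of all 41345 probe sets, 39 of the 16010 without an annotation entry were higher in 4E-T than in IgG and 967 were lower. With the normalization set as a term 190 were higher and 1253 lower. Of the 1814 probe sets with several symbols 5 were higher and 56 lower, and 54 and 104 with that term. Of the 23521 with a single symbol 209 were higher and 210 lower, and 1304 and 537 with that term. What the unannotated probe sets measure was not tested.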

How the results depend on the processing

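The fits with the normalization set as a term and of the 8 other arrays were chosen after the result was seen, and the other alternatives were planned. Counts are given for 4E-T over IgG (299 with group alone), 4E-T over input (1361), IgG over input (1206) and 4E-T over both (94), in that order, and the cause of a change was not tested unless stated.

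With the normalization set as a term the counts were 2326, 4274, 3688 and 948, and in the 8 other arrays 1911, 3567, 3471 and 783. Median centring gave 1510, 2662, 2725 and 552, cyclic loess 1686, 3293, 3389 and 498, and repeated quantile normalization 1732, 3228, 3489 and 501. Array weights gave 3049, 5733, 4041 and 1310, and a trend and robust variance 685, 2046, 1864 and 215. Genes above the median level gave 779, 2382, 2125 and 263. Only the groups compared in the fit gave 195, 753 and 48 for the first, second and last, with fewer arrays behind the variance. A minimum log2 difference of 1 left 856 and 748 against input, by construction. All probe sets gave 1486 for 4E-T over IgG, with 253 higher and 1233 lower, since most added lower calls had no symbol. The other counts under these settings, and those with the mean of a gene's probe sets, stayed within 1.5 times. Leaving out 1 array gave 90 to 672, 371 to 2005, 444 to 1866 and 23 to 185.

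With the replicate number as a block the counts were 2454, 4510, 4120 and 968, and as a random block 2789, 4695, 4567 and 993 (consensus correlation 0.706). The block spends more degrees of freedom (4 residual against 7) but takes up the difference of the arrays numbered 1. For 4E-T over input, where the numbers met the pairing criterion, it changed the calls printed with that comparison, Neurod4, Eif4enif1, Neurog1, Neurod1 and the ventral and cell cycle lists, and no other call there among the lists and the genes examined with the block for that comparison. Genes named as list members were examined with the block for 4E-T over IgG only. For the other comparisons the criterion was not met. Over all pairs of arrays in different groups, same-number correlations of deviations ran from -0.067 to 0.623 and different-number ones from -0.451 to 0.269, and within the 8 arrays from 0.0085 to 0.247 and from -0.197 to 0.0763.

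The correlation across genes of the differences against input (0.527) became 0.335 over all probe sets, 0.606 over genes above the median level and 0.584 in the 8 arrays, and 0.455 to 0.604 without 1 array. It moved by less than its spread over the arrays left out (SD 0.0456) with cyclic loess (0.560), the normalization set (0.550) and the replicate block removed (0.542).

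The list tests called 39 lists over the 3 comparisons with group alone, 0 with an estimated correlation, where limma's camera allows for correlated genes, and 6 with fry, all lower. Unlike camera, which sets a list against the other genes, fry tests it against no change, so that the shift of all genes enters and its calls are not of the same kind. They called 38 over genes above the median level, 42 with cyclic loess, 40 with the replicate block, 42 with the normalization set, 43 in the 8 arrays and 37 to 43 without 1 array. The direction changed together with a call for 2 lists in 4E-T over IgG. The replication-dependent histones had a median of 0.13 with group alone (adjusted p = 0.692) and were called lower in the 8 arrays (-0.26, adjusted p = 0.0226) and without 4E-T 1 (-0.26, adjusted p = 0.0200), and leaving out 1 array gave -0.26 to 0.25. The developmental transcription factors were called higher with group alone and pointed down with fry without a call (list median 0.12 relative to the other genes, adjusted p = 0.999). Their mean without that reference was -0.02, so the direction follows from the other question that fry asks. Lists not called in either setting changed direction too, among them oxidative phosphorylation (0.18 with group alone, -0.09 in the 8 arrays) and translation factors (0.08 and -0.01).

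Of the differences of named genes, 37 gained a call with the normalization set as a term, 31 in the 8 arrays and 43 with the replicate block, and none lost one in any of these. Median centring gave 27 more, cyclic loess 30, array weights 46 and a trend and robust variance 18, while only the groups compared took away 12. Leaving out 1 array took away 165 calls over all genes, comparisons and arrays and added 18. No detection call or background level was given with the values, so how far dim probe sets limit the calls was examined only through the genes above the median level.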

Other observations

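Tests chosen after the result was seen were those of families of genes sharing the start of a symbol, the nuclear RNA test for the small noncoding RNAs and every value with the normalization set as a term. The list medians had also been seen before the other tests were chosen, and the idea of unspliced host transcripts came from called genes, which were left out of its test.

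Families sharing the start of a symbol were examined among protein-coding genes, 224 families of at least 10 genes in each comparison. The camera test called 14 of them in 4E-T over IgG, 35 in 4E-T over input and 29 in IgG over input, and 6, 35 and 30 with the normalization set as a term. With an estimated correlation it called 0 in either fit, so none stands on its own. The mitochondrial ribosomal protein genes Mrpl were lower in both precipitates than in input. Of 43, 20 were lower in 4E-T over input (median -0.73, adjusted p = 1.79e-21, adjusted p = 0.714 with an estimated correlation) and 26 in IgG over input (-1.29, 1.21e-40, adjusted p = 0.266 with an estimated correlation). Of 28 Mrps genes 12 and 17 were lower. Of 11 proteasome genes Psmb 7 were lower in 4E-T over input (median -0.94) and 5 in IgG over input. On the higher side of 4E-T over input, of 10 frizzled receptor genes Fzd 4 were higher (median 0.89, adjusted p = 4.67e-07, adjusted p = 0.994 with an estimated correlation), and of 12 protocadherin genes Pcdh 3 (median 0.77), with 8 and 7 higher with the normalization set as a term.

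Small noncoding RNAs were lower in 4E-T than in IgG (list median -0.25). By annotated class, the median relative to all genes was -1.26 for the 80 snoRNAs and -0.19 for the 478 microRNA genes. Of 10000 random lists of other tested genes matched on mean level, 0% had a median as low as that of the list. A dim level alone therefore did not account for it among genes with a symbol. Probe sets without an annotation entry were not in those lists. Their median was -0.417 (mean level 4.12), against -0.196 for single-symbol probe sets. The small noncoding list, not set against other genes, lay at -0.440 (mean level 3.76). Background shared with unannotated probe sets thus stays open. More nuclear RNA of every kind in the IgG precipitate may contribute: the nuclear long noncoding list had a median of -0.587, with a bootstrap interval from -0.860 to -0.291, but that list was also lower in 4E-T than in input (-0.58), so a loss from the 4E-T precipitate stays open. Probes that read unspliced host transcripts could contribute as well, since 0.43% of matched lists had a median as low as that of the snoRNA host genes. The interval of the 30 host genes relative to all genes, -0.238 to 0.0801, included 0, as did that with the normalization set as a term (-0.350 to 0.0189, with 0.28% of matched lists as low), so this stays open.

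Zfp genes were higher in 4E-T than in IgG (list median 0.41). Dim probe sets as the whole cause were excluded, since 0% of 10000 matched lists had a median as high. Cross-hybridization between neighbouring genes named Zfp was not the whole cause. The 156 Zfp genes with no other Zfp gene among the 5 genes on each side had a median of 0.27, interval 0.167 to 0.359. The 206 with such a neighbour lay at 0.55, interval 0.444 to 0.654. Paralogs with other symbols, farther away or elsewhere were not covered, so cross-hybridization with them, and a part from neighbours, stays open. The intervals come from resampling genes, not arrays. That 4E-T associates with these RNAs in the cell stays a hypothesis, found and tested on the same arrays.

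Other splits of the arrays were counted for each comparison, the real one included. For 4E-T over IgG 1 of 10 splits gave as many calls as the real 299, the highest other was 0, and 10 splits are too few for a share under 0.05. With the normalization set as a term the values were 2326 and 0. For 4E-T over input 1 of 35 splits reached the real 1361, and the highest other was 350, which excludes chance only if all 7 arrays can be exchanged. The numbers met the pairing criterion here, with the highest correlation in the pair numbered 1, which does not establish that they mark pairs. Of the splits only 8 part all 3 numbered pairs and 20 keep 1 lower array on each side. Both are too few for a share under 0.05, with a highest other of 0 in each. The split with 350 calls set input 1 with the 4E-T arrays, against inputs 2, 3 and 4, so that both arrays of the lower set stayed on one side. With the normalization set as a term the values were 4274 and 2713. For IgG over input 1 of 35 reached 1206 and the highest other was 1, which excludes chance under the same condition, while the 20 splits that keep input 1 in the group of 4 are too few for a share under 0.05, with a highest other of 0. With that term the values were 3688 and 2583, the latter for inputs 2, 3 and 4 against the IgG arrays with input 1. For the genes higher than both, 1 of 20 splits reached 94, the highest other was 56, with the labels 4E-T and IgG exchanged, and 20 splits are too few for a share under 0.05. With that term the values were 948 and 302.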
